A study of Mus musculus with 24 samples.

How the data were processed

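The libraries came from bone marrow-derived macrophages of male C57BL/6 mice, wild-type (WT) or deficient in the G protein-coupled receptor GPR35 (KO). The cells were grown with M-CSF and, on day 7, left untreated (Cont) or treated for 4 h with lysophosphatidic acid (LPA, 10 µM) or lipopolysaccharide (LPS, 10 ng/mL). Each of the 6 groups had 4 replicates, which gave 24 libraries. According to the submitters' processing notes, the stranded mRNA libraries were sequenced as paired 51-base reads and aligned with STAR 2.5.2a to the mouse assembly mm10. The counting tool, its strand setting and the gene annotation are not given in the sources used here. Reads shared by near-identical genes, such as the Ifit, H2 and actin families, depend on how the counting tool treated them. Gene positions were taken from the RefSeq gene table of GRCm38.p6, the assembly that mm10 stands for.

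The deposited table of gene counts was used as it stood, and every one of its columns was matched to a sample. It held 11590 genes, of which 9 had no symbol. All of them reached 0.5 CPM (counts scaled by library size) in at least 6 libraries, and the smallest total of a gene was 170 counts, so the table had already been filtered on abundance before deposition. None of the 13 mitochondrially encoded genes was in the table, and the share of mitochondrial reads was not analysed here. Genes removed by that earlier filter were not analysed here. The 36 pairs of replicates within a group differed by a chi-square of 4.11 to 77.4 per degree of freedom, so no library was a copy of another in its group.

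Differential expression was tested with edgeR 4.0.16 (TMM size factors, robust quasi-likelihood F test) in one model with a mean for each of the 6 groups, over all 24 libraries, which left 18 residual degrees of freedom. Nothing was removed by filterByExpr. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 within each comparison. The 9 comparisons were LPA and LPS against untreated cells in each genotype, KO against WT in each treatment, and the difference of each treatment effect between the genotypes (KO minus WT, called the interaction below). A log2 change is followed by its standard error, and a CPM value by the standard deviation over 4 libraries. TMM factors lay between 0.739 and 1.18, and the common biological coefficient of variation was 9.91%.

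Genes were named by a rule. It took, among genes with an adjusted p below 0.05, a mean of at least 2 CPM and an official symbol, the 8 largest rises and the 8 largest falls in which all 4 libraries of one group lay outside the range of the other. In an interaction it took the 6 largest each way without the condition on ranges. From each gene list it took up to 4 members with the smallest adjusted p, whether or not they passed the test. Gpr35 was reported throughout and Tnf in the LPA comparisons. Some genes that the rule picked are not reported here.

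Gene lists were written from general knowledge of the field before the data were examined. They covered NF-kB target genes, pro-inflammatory cytokines, chemokines, interferon-stimulated genes, immediate-early genes, SRF and YAP target genes, sterol biosynthesis, LXR target genes, steroid hormone synthesis, glycolysis and HIF-1 target genes, alternative activation genes, NRF2 target genes, the unfolded protein and integrated stress response, cell cycle genes, antigen presentation, and LPA receptors and LPA metabolism. Further lists held macrophage identity genes, markers of neutrophils and granulocyte precursors, dendritic cells, T, NK and B cells, mast cells and basophils, erythroid cells and megakaryocytes, stromal cells and fibroblasts, and osteoclasts, and the genes near Gpr35 on chromosome 1. With the mitochondrially encoded genes there were 26 lists, of which 25 had measured members. Each list was tested against all other genes with camera (limma 3.58.1, voom weights) with a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. Adjustment was over the 25 lists of a comparison. The counts of members that rose or fell used adjustment over all genes, and a second count used adjustment over the list alone.

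A response score of a library was the mean log2 CPM of the genes called for the treatment effect averaged over both genotypes, centred per gene and signed by the direction of that effect. The difference of the score change between genotypes was tested by exact permutation: genotype labels were exchanged within each treatment, after the genotype means had been subtracted, in all 4900 arrangements. Alternatives fixed before the data were examined were DESeq2 1.42.0, median-ratio size factors, no filter, a stricter filter (50 counts), a fit of only the compared groups, counts thinned at random to the smallest library (15167683 counts), leaving out each library in turn, and a term for the replicate number (within each genotype for treatments, and in a fit of the 2 groups between genotypes). Because the treated and untreated libraries share the untreated group, the overlap of LPA and LPS genes was compared with simulated counts and with separate untreated libraries for each treatment. Scaling by library totals alone, the rotation test fry (a list against no change, so not a repeat of camera's test against other genes), and camera in the fit with replicate numbers were added after the results had been seen. The naming of counts without particular libraries was also chosen then.

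Nothing in the sample descriptions says that libraries with the same replicate number share a culture. After subtraction of the group means, libraries with the same number correlated above 0.1 in all 4 pairs for WT Cont and LPA (0.211 to 0.626), KO Cont and LPA (0.281 to 0.772), KO Cont and LPS (0.196 to 0.511) and KO LPA and LPS (0.114 to 0.525). The lowest such pair for WT Cont and LPS was 0.0938, and numbers did not pair across genotypes (-0.576 to -0.0583 for the untreated groups). Nothing says that replicates came from separate animals or cultures either, so p-values measure only the spread between these samples. The sample descriptions list 2 sequencing lanes for each WT library and 1 for each KO library, so lanes and genotype cannot be told apart by the model.

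In counts simulated from the measured mean levels, library sizes and dispersions, 100 genes were given a 1.5-fold and 100 a 2-fold LPA effect in WT alone. The model found 79 and 96 of them in WT, with 8 of 11390 unchanged genes called. For the interaction it found 62 and 84, with 8 unchanged genes called. Work was done in R 4.3.3 and Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9).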

Results

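The libraries held a receptor knockout with little of its transcript left. Gpr35, which encodes the G protein-coupled receptor GPR35 (chromosome 1, 92948052 to 92986391, GRCm38.p6), was a low transcript in wild-type (WT) bone marrow-derived macrophages, at 2.61 ± 0.214 CPM without treatment (mean ± SD, n = 4, with 107, 133, 112 and 111 counts). After 4 h of lysophosphatidic acid (LPA) it was 2.07 ± 0.697 CPM (122, 64, 91 and 54 counts). After lipopolysaccharide (LPS) it was 0.417 ± 0.150 CPM (11, 8, 17 and 10 counts). In GPR35-deficient (KO) macrophages it was 0.133 ± 0.0710 CPM without treatment (4, 1, 2 and 5 counts) and 0.110 ± 0.0844 CPM with LPA (4, 0, 3 and 2 counts). It was not detectable in any of the 4 KO libraries with LPS. Scaled by library totals, 5.43% of the WT level remained without treatment and 5.88% with LPA. With LPS, 0 of 68712497 KO counts fell on Gpr35. With a floor of 3 counts for the group (0.0437 CPM), the KO level with LPS was at least 7.27-fold below the 0.318 CPM of WT. The edgeR log2 change of Gpr35 in KO was -4.20 ± 0.38 without treatment (adjusted p = 7.1e-06) and -4.14 ± 0.41 with LPA (adjusted p = 2.1e-07). In WT cells, LPS lowered Gpr35 by a log2 change of -2.63 ± 0.29 (edgeR adjusted p = 5.1e-08). No change with LPA was called in WT (-0.33 ± 0.23, edgeR adjusted p = 0.25). None was called in KO cells either (-0.27 ± 0.68, edgeR adjusted p = 0.93), where the remaining counts are too few to show that it was absent.

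**Figure D1:**
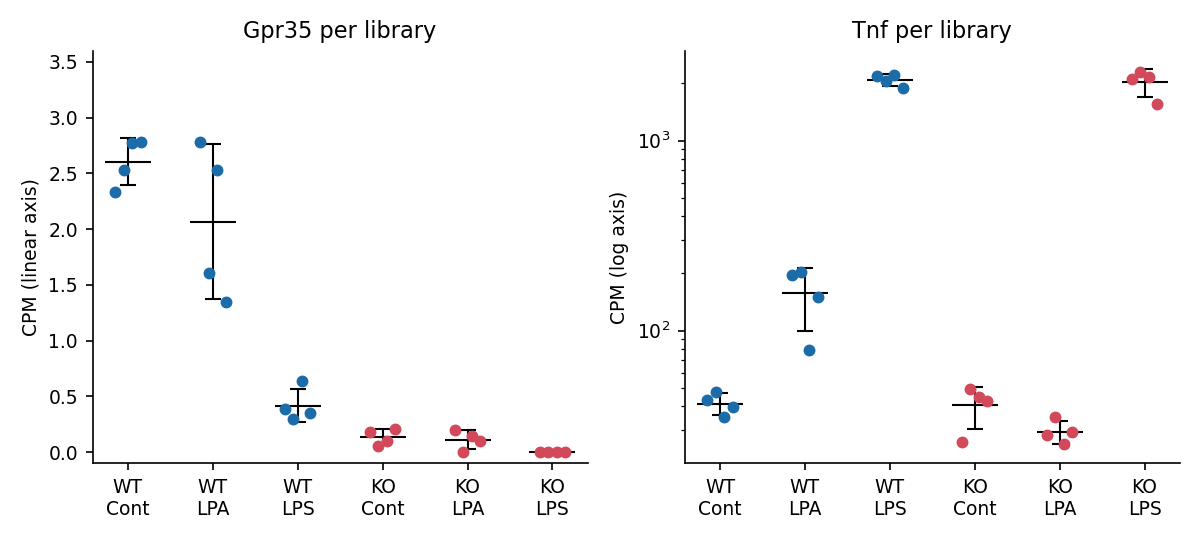
Levels of Gpr35 (linear axis) and Tnf (log axis) in CPM in the 6 groups; points are libraries and bars are the mean ± SD of 4. Gpr35 was 2.61 CPM in untreated WT and 0.133 CPM in untreated KO, and Tnf rose with LPA from 41.3 to 156.9 CPM in WT.

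Between untreated KO and WT macrophages no transcript other than Gpr35 was called. It was the 1 gene of 11590 that passed (DESeq2 also called 1, and 314 had an unadjusted p below the same threshold). None of the 20 measured genes near Gpr35 on chromosome 1 was called, over all genes or adjusted over the list alone. None of 24 interferon-stimulated genes was called, with a median log2 difference of -0.30 (Mx2 -0.47 ± 0.17, Ifit1 -0.43 ± 0.16, Ddx58 -0.28 ± 0.10, all edgeR adjusted p = 1.0). The scores of this list were -1.56 and -1.41 in KO Cont 1 and 3, while KO Cont 2 and 4 (-0.857 and -0.682) lay within the WT range (-0.871 to -0.585). Camera called that list with the preset correlation (adjusted p = 2.9e-23) and not with an estimated one (adjusted p = 0.247). LXR target genes (median -0.12, adjusted p = 0.0011 preset and 0.174 estimated) and antigen presentation (-0.18, adjusted p = 8.0e-05 preset and 0.457 estimated) were called likewise. So were NF-kB target genes (-0.04, camera adjusted p = 0.0334 preset and 0.727 estimated). Cell cycle genes (0.26, camera adjusted p = 0.00568 preset and 0.727 estimated) and neutrophil markers (0.21, adjusted p = 0.00288 preset and 0.727 estimated) were called as higher. None of their members was called over all genes or over the list alone. The rotation test fry, which tests a list against no change instead of against other genes, called none of these lists. The KO libraries were shallower (15.2 to 21.5 M counts) than the WT libraries (32.0 to 46.7 M counts), and the sequencing lanes went with the genotype.

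LPA gave WT macrophages an inflammatory profile of moderate size. Tnf, the gene of the cytokine TNF (chromosome 17, 35199367 to 35202007, GRCm38.p6), rose from 41.3 ± 5.36 to 156.9 ± 57.5 CPM, a log2 change of 1.93 ± 0.23 (n = 4 per group, edgeR adjusted p = 2.3e-06). Acod1, which encodes the enzyme that makes itaconate, rose by 2.53 ± 0.22 (adjusted p = 7.4e-08) from 115.8 to 666.6 CPM. Ak4, which encodes a mitochondrial adenylate kinase, rose by 3.41 ± 0.30 (adjusted p = 6.0e-08). Gpr84, a receptor for medium-chain fatty acids, rose by 2.29 ± 0.18 (adjusted p = 2.6e-08). The neutrophil chemoattractant gene Cxcl2 (2.19 ± 0.32, adjusted p = 2.9e-05) and the activating myeloid receptor gene Tarm1 (2.51 ± 0.27, adjusted p = 1.1e-06) rose too. Among the largest falls were Eps8, which encodes an actin-regulating adaptor (-2.63 ± 0.23, adjusted p = 3.7e-08, 10.8 to 1.75 CPM), and Clec10a, a C-type lectin gene of alternatively activated macrophages (-2.20 ± 0.39, adjusted p = 2.0e-04). In each of these genes except Tnf, a separation of all 4 treated from all 4 untreated libraries was part of the naming rule. In all, 5165 genes changed (44.6%, 2723 rose and 2442 fell), 324 of them at least 2-fold. With scaling by library totals alone, 40.3% of the called genes rose (2077 up, 3082 down), against 52.7% here, so the balance of rises and falls depends on the scaling. The count lay between 3792 without WT LPA 2 and 6083 without WT LPA 3, the library with the weakest response.

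In WT cells with LPA, 16 of 18 NF-kB target genes rose and none fell (16 adjusted over the list alone, median 0.69), among them Sod2 (1.55 ± 0.12, edgeR adjusted p = 1.6e-08) and Traf1 (1.69 ± 0.16). Camera called the list with the preset correlation (adjusted p = 3.0e-10) and not with an estimated one (adjusted p = 0.175). Of 13 pro-inflammatory cytokines 7 rose and none fell (7 over the list alone, median 0.59, camera adjusted p = 0.00803 preset and 0.358 estimated). Tnfsf9 rose by 1.32 ± 0.18 and Il1b by 1.05 ± 0.26. Of 18 chemokines 13 rose and none fell (13 over the list alone, median 0.75, camera adjusted p = 5.2e-04 preset and 0.268 estimated). Ccl4 rose by 1.01 ± 0.20 and Ccl5 by 0.91 ± 0.16. Interferon-stimulated genes rose in 22 of 24 and fell in none (22 over the list alone, median 0.72, camera adjusted p = 9.9e-08 preset and 0.358 estimated). Isg20 rose by 1.14 ± 0.17 and Ifit1 by 0.94 ± 0.16. Of 21 immediate-early genes 8 rose and 1 fell (8 and 1 over the list alone, median 0.38, camera adjusted p = 0.0298 preset and 0.429 estimated). Dusp4 rose by 1.52 ± 0.25 and Fos by 0.75 ± 0.10. SRF and YAP target genes, which follow the actin cytoskeleton, rose in 9 of 14 and fell in none (9 over the list alone, median 0.49, camera adjusted p = 2.6e-04 preset and 0.175 estimated). Tpm4 rose by 1.13 ± 0.09 and Vcl by 0.71 ± 0.09.

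Metabolic transcripts moved with LPA in WT as well. Sterol biosynthesis genes rose in 18 of 22 and fell in none (19 over the list alone, median 0.87, camera adjusted p = 1.2e-06 preset and 0.377 estimated). Hsd17b7, a gene of the later steps of cholesterol synthesis, rose by 1.42 ± 0.25, and Insig1, which encodes a sterol sensor, by 0.84 ± 0.16. Glycolysis and HIF-1 target genes rose in 20 of 22 (20 over the list alone, none fell, median 0.61, camera adjusted p = 3.0e-10 preset and 0.175 estimated). The glucose transporter gene Slc2a1 rose by 1.31 ± 0.14 and the prolyl hydroxylase gene Egln3 by 2.73 ± 0.29. NRF2 target genes rose in 14 of 17 (14 over the list alone, none fell, median 0.63, camera adjusted p = 2.5e-07 preset and 0.268 estimated). The cystine transporter gene Slc7a11 rose by 1.94 ± 0.23 and Txnrd1 by 1.03 ± 0.12. Genes of the unfolded protein and integrated stress response rose in 10 of 18 (13 over the list alone, none fell, median 0.33, camera adjusted p = 0.00351 preset and 0.358 estimated). Asns rose by 1.20 ± 0.25 and Atf4 by 0.59 ± 0.12. Alternative activation genes went the other way: 7 of 12 fell and none rose (7 over the list alone, median -0.42, camera adjusted p = 0.0111 preset and 0.175 estimated). The mannose receptor gene Mrc1 changed by -0.88 ± 0.08 and Cd163 by -1.61 ± 0.38. LXR target genes were mixed, with 4 up and 7 down of 15 (4 and 7 over the list alone, camera adjusted p = 0.588 preset and 0.739 estimated, Nr1h3 0.76 ± 0.20, Arl4c -0.48 ± 0.10). So was antigen presentation, with 4 up and 3 down of 18 (4 and 3 over the list alone, camera adjusted p = 0.912 preset and 0.961 estimated, Ciita -1.25 ± 0.23, Nlrc5 0.61 ± 0.14). Among 28 cell cycle genes 1 fell (1 over the list alone, Mcm4 -0.36 ± 0.10, camera adjusted p = 0.841 preset and 0.957 estimated). Of 2 measured genes of steroid hormone synthesis Fdxr fell (-0.47 ± 0.16, 1 over the list alone, camera adjusted p = 0.841 preset and 0.957 estimated).

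Genes of LPA receptors and LPA metabolism rose in 6 of 12 and fell in 2 in WT with LPA (7 and 3 over the list alone, camera adjusted p = 0.16 preset and 0.268 estimated). The receptor gene Lpar1 rose by 1.23 ± 0.18 (edgeR adjusted p = 2.3e-05) and the lipid phosphatase gene Plpp1 by 1.40 ± 0.21. Macrophage identity genes rose in 4 of 20 and fell in 3 (4 and 2 over the list alone, camera adjusted p = 0.841 preset and 0.957 estimated). Cd14 rose (1.24 ± 0.13) and the efferocytosis receptor gene Mertk fell (-0.65 ± 0.09). All 3 measured dendritic cell markers fell (3 over the list alone, Kmo -1.82 ± 0.26, camera adjusted p = 0.0236 preset and 0.268 estimated). Both measured megakaryocyte markers, the platelet chemokine genes Pf4 (0.92 ± 0.11) and Ppbp (1.66 ± 0.30), rose (both over the list alone, camera adjusted p = 0.0236 preset and 0.175 estimated). Of neutrophil markers 1 of 13 fell (0 over the list alone, Ltf -0.64 ± 0.25, camera adjusted p = 0.102 preset and 0.739 estimated). Of 2 T, NK and B cell markers 1 fell (2 over the list alone, Cd4 -0.43 ± 0.15, camera adjusted p = 0.245 preset and 0.441 estimated). The only measured mast cell marker, Hdc, rose (0.77 ± 0.16, 1 over the list alone, camera adjusted p = 0.246 preset and 0.358 estimated). Of 6 stromal markers 1 rose (1 over the list alone, Cdh5 1.63 ± 0.37, camera adjusted p = 0.841 preset and 0.957 estimated). Osteoclast markers rose in 1 and fell in 2 of 8 (1 and 2 over the list alone, Itgb3 -1.29 ± 0.25, Tnfrsf11a 0.49 ± 0.09, camera adjusted p = 0.912 preset and 0.957 estimated). Near Gpr35, 2 of 20 genes rose and 3 fell (2 and 2 over the list alone, D2hgdh -0.46 ± 0.07, camera adjusted p = 0.68 preset and 0.767 estimated). None of the 13 lists that camera called with the preset correlation had an adjusted p below the threshold with the estimated correlation (0.175 to 0.429), so a difference of these lists from other genes was not established. Fry, against no change, called all 13, where 44.6% of all genes had changed.

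KO macrophages gave a smaller and different answer to LPA. Tnf was 40.6 ± 10.1 CPM without and 29.4 ± 4.08 CPM with LPA and was not called as changed (-0.47 ± 0.23, n = 4 per group, edgeR adjusted p = 0.42). Rises included Olfml3, which encodes a secreted olfactomedin-like protein (2.24 ± 0.23, adjusted p = 1.0e-05), and Pald1 (1.57 ± 0.20, adjusted p = 9.8e-05). The chemokine gene Cxcl14 (1.39 ± 0.19, adjusted p = 1.4e-04) and the transglutaminase gene Tgm2 (1.33 ± 0.21, adjusted p = 7.3e-04) rose too. Falls included the interferon-induced chemokine gene Cxcl10 (-1.11 ± 0.21, adjusted p = 4.7e-03), the early activation marker gene Cd69 (-0.90 ± 0.17, adjusted p = 2.8e-03) and the anti-inflammatory cytokine gene Il10 (-0.87 ± 0.19, adjusted p = 0.011). In all, 304 genes changed (2.62%, 181 rose and 123 fell), 26 of them at least 2-fold, and 1472 had an unadjusted p below the threshold. DESeq2 called 462. A term for the replicate number, which pairs these libraries, gave 554 (6150 for LPA in WT), with 300 of the 304 among them. Leaving out single libraries gave 168 (without KO LPA 3), 184 (without KO Cont 4), 190 (without KO Cont 3) and up to 310 genes.

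**Figure D2:**
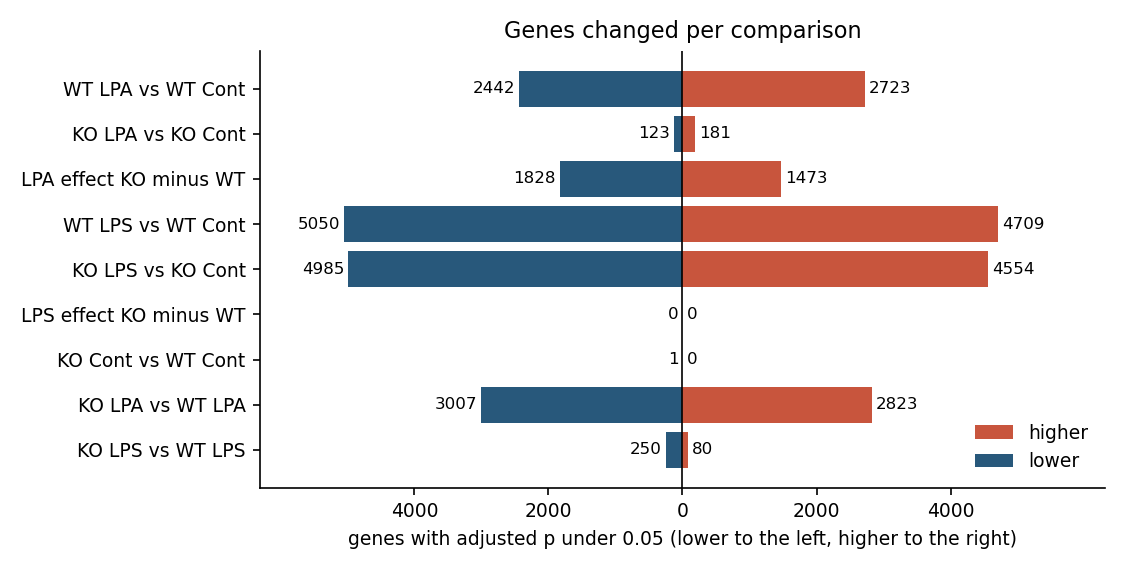
Number of genes that rose (right) or fell (left) at an edgeR adjusted p below 0.05 in each comparison, with bars for the counts. LPA changed 5165 genes in WT and 304 in KO, LPS 9759 and 9539, and with scaling by library totals alone most LPS calls were falls (7847 and 7627).

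In KO cells with LPA, 3 of 18 NF-kB target genes fell and none rose (5 fell over the list alone, median -0.14, camera adjusted p = 3.6e-05 preset and 0.501 estimated). They were Nfkbiz (-0.57 ± 0.09, edgeR adjusted p = 5.9e-04), Cd40 (-0.70 ± 0.15) and Ikbke (-0.27 ± 0.07). No interferon-stimulated gene was called among all genes, and 7 of 24 fell when adjusted over the list alone (median -0.29, camera adjusted p = 9.2e-07 preset and 0.501 estimated, Rsad2 -0.71 ± 0.20, Ifit1 -0.55 ± 0.16). By replicate number, the score of this list rose in KO 1 (-1.564 to -1.255). It fell in KO 2 (-0.857 to -1.365), KO 3 (-1.41 to -1.714) and KO 4 (-0.682 to -1.4). Glycolysis and HIF-1 target genes rose in 4 of 22 (6 over the list alone, none fell, median 0.18, camera adjusted p = 1.2e-06 preset and 0.501 estimated). Vegfa rose by 1.08 ± 0.20 (edgeR adjusted p = 3.6e-03) and Hk2 by 0.43 ± 0.08. Of 12 alternative activation genes 2 fell, Mrc1 (-0.53 ± 0.08) and Il10 (1 rose and 3 fell over the list alone, median -0.40, camera adjusted p = 0.00774 preset and 0.452 estimated, fry adjusted p = 0.0326). This was the only 1 of the 11 lists called by camera that fry called against no change. With the replicate number in the fit, camera with an estimated correlation called the glycolysis list (adjusted p = 0.0151) and the alternative activation list (adjusted p = 0.0493). Immediate-early genes rose in 2 of 21 (3 over the list alone, Fos 0.71 ± 0.11, Nr4a2 1.20 ± 0.29, camera adjusted p = 0.0407 preset and 0.501 estimated). SRF and YAP target genes rose in 2 of 14 (3 up and 1 down over the list alone, Myh9 0.35 ± 0.06, Thbs1 1.68 ± 0.37, camera adjusted p = 0.00653 preset and 0.501 estimated).

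Chemokines were mixed in KO cells with LPA, with Cxcl14 and Cxcl16 (0.32 ± 0.06) up and Cxcl10 down (2 up and 3 down over the list alone, camera adjusted p = 0.457 preset and 0.831 estimated). So were LXR target genes, with Mylip (0.31 ± 0.08) up and Lpl (-0.45 ± 0.10) down (3 up and 1 down over the list alone, camera adjusted p = 0.271 preset and 0.501 estimated). No cytokine gene was called over all genes or over the list alone (camera adjusted p = 0.467 preset and 0.831 estimated). Among NRF2 target genes Gclm rose (0.48 ± 0.13, 2 over the list alone, camera adjusted p = 0.00101 preset and 0.501 estimated). In the unfolded protein and integrated stress response Herpud1 fell (-0.68 ± 0.08, edgeR adjusted p = 2.6e-05, 1 over the list alone, camera adjusted p = 0.0358 preset and 0.525 estimated). Sterol biosynthesis had 0 called members (0 over the list alone, median -0.34, camera adjusted p = 5.1e-05 preset and 0.501 estimated). Antigen presentation had none either (0 over the list alone, median -0.14, camera adjusted p = 0.0104 preset and 0.501 estimated). Of 6 stromal and endothelial markers Pecam1 rose (1.29 ± 0.31, edgeR adjusted p = 0.027, 6.78 ± 2.64 to 16.6 ± 7.21 CPM). In that list 3 rose over the list alone (median 1.27, camera adjusted p = 0.00653 preset and 0.501 estimated). Col1a1 (1.99 ± 0.75) and Col1a2 (2.12 ± 0.74) were higher in the mean without passing the test, at 2.10 ± 1.35 and 2.26 ± 1.44 CPM in KO with LPA. Of the 304 genes, 159 also changed in WT, 110 of them in the same direction (68.4 if the calls were independent) and 49 in the opposite one.

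The LPA effect itself differed between genotypes in 3301 genes, with 1473 effects higher and 1828 lower in KO. Among the named genes the difference was largest for Acod1 (-2.81 ± 0.31, n = 4 per group, edgeR adjusted p = 7.0e-06), which was 105.6 CPM without and 86.6 CPM with LPA in KO. Tnf (-2.39 ± 0.32, adjusted p = 5.1e-05), Cxcl2 (-2.48 ± 0.47, adjusted p = 1.0e-03) and the formyl peptide receptor genes Fpr1 (-2.28) and Fpr2 (-2.30 ± 0.28, adjusted p = 2.1e-05) behaved alike. Higher in KO was the LPA effect on Eps8 (1.91 ± 0.30, adjusted p = 1.9e-04, 13.97 to 8.51 CPM in KO) and the organic anion transporter gene Slco2b1 (1.83 ± 0.22, adjusted p = 1.5e-05). Across all genes the LPA effects of the 2 genotypes were uncorrelated (r = -0.01, genes are not independent replicates). With scaling by library totals 59.9% of the calls were higher in KO, against 44.6% here. DESeq2 called 3585 genes, a term for the replicate number gave 4328, and leaving out 1 library gave 2259 to 4632.

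**Figure D3:**
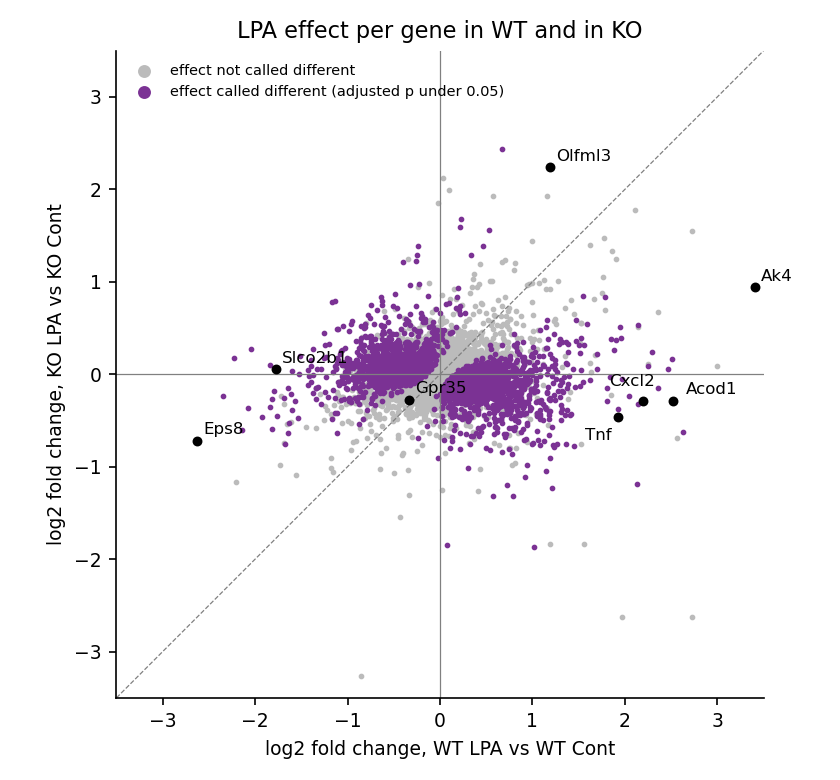
Log2 change with LPA in KO (vertical) against WT (horizontal); each point is a gene, and purple points are the 3301 genes whose LPA effect differed between genotypes. Points spread along the WT axis and little along the KO axis (r = -0.01); with scaling by library totals alone the share of effects higher in KO went from 44.6% to 59.9%.

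A response score over 2575 LPA genes gave the size of the answer per library. It rose by 0.5004 (SE 0.0755) in WT and by 0.124 (SE 0.0306) in KO, which is 24.7% of the WT response. These genes were chosen and signed by their mean effect over both genotypes in the same libraries. Genes on which KO opposed WT were thus less likely to be chosen, which favours a rise of the score in KO. The 24.7% holds for these genes only, and across all genes the LPA effects were uncorrelated (r = -0.01). The difference of -0.377 had an exact permutation p of 0.00122 over 4900 arrangements. Leaving out single libraries gave -0.457 to -0.339. With libraries paired by replicate number the exact permutation p was 0.0286, the smallest value that 70 arrangements allow. WT libraries with LPA scored 0.171 to 0.489 and WT libraries without it -0.185 to -0.108. KO libraries scored -0.0692 to -0.0233 with LPA and -0.243 to -0.101 without.

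**Figure D4:**
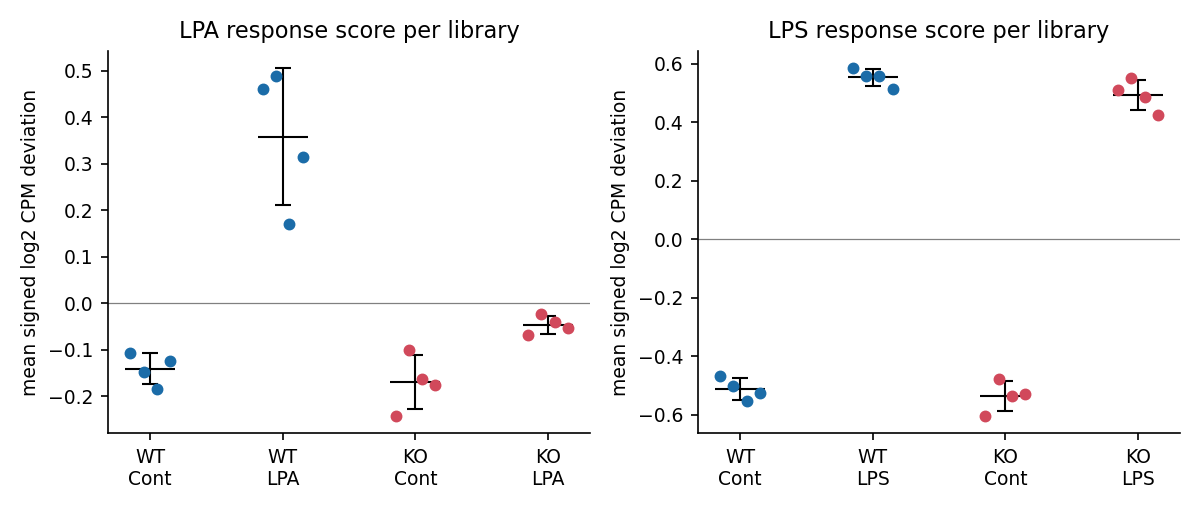
Response score (mean signed log2 CPM, centred) per library for the LPA genes and the LPS genes; points are libraries and bars are the mean ± SD of 4. The LPA response was 0.5004 in WT and 0.124 in KO, the LPS response 1.07 and 1.03.

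In 16 of 18 NF-kB target genes the LPA effect was lower in KO (16 over the list alone, median -0.94, camera adjusted p = 6.9e-14 preset and 0.353 estimated). The difference was -1.18 ± 0.12 for Nfkbiz and -1.64 ± 0.17 for Sod2 (both edgeR adjusted p = 4.9e-06). The same held for 23 of 24 interferon-stimulated genes (24 over the list alone, camera adjusted p = 9.4e-12 preset and 0.416 estimated, Ifit1 -1.49 ± 0.23, Rsad2 -1.77 ± 0.28). Of 22 sterol biosynthesis genes 17 had a lower effect (20 over the list alone, median -1.19, camera adjusted p = 6.5e-09 preset and 0.416 estimated, Insig1 -1.18 ± 0.23, Fdps -1.66 ± 0.33). Chemokines were lower in 8 and higher in 1 (11 and 1 over the list alone, median -1.05, camera adjusted p = 0.00155 preset and 0.416 estimated, Cxcl10 -2.04 ± 0.30, Ccl4 -1.76 ± 0.30). Cytokines were lower in 5 (5 over the list alone, median -0.72, camera adjusted p = 0.0147 preset and 0.416 estimated, Csf1 -1.16 ± 0.22). Glycolysis and HIF-1 target genes were lower in 12 (18 lower and 1 higher over the list alone, median -0.40, camera adjusted p = 3.0e-05 preset and 0.416 estimated, Slc2a1 -0.97 ± 0.20, Pgk1 -0.68 ± 0.13). NRF2 target genes were lower in 10 (12 over the list alone, median -0.60, camera adjusted p = 2.8e-04 preset and 0.416 estimated, Txnrd1 -0.79 ± 0.17). The unfolded protein and integrated stress response was lower in 7 (10 over the list alone, median -0.47, camera adjusted p = 3.8e-04 preset and 0.416 estimated, Herpud1 -0.80 ± 0.11, Atf4 -0.71 ± 0.17). SRF and YAP target genes were lower in 7 and higher in 1 (7 and 1 over the list alone, median -0.32, camera adjusted p = 0.0147 preset and 0.416 estimated, Tpm4 -1.04 ± 0.13, Vcl -0.76 ± 0.13). Lpar1 (-1.995 ± 0.30), Cd14 (-0.80 ± 0.19) and Nlrc5 (-0.78 ± 0.20) also had a lower effect in KO, Mertk (0.65 ± 0.13) and Lpar6 (0.91 ± 0.22) a higher one. None of these 9 lists passed with the estimated correlation, and fry called all of them against no change.

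**Figure D5:**
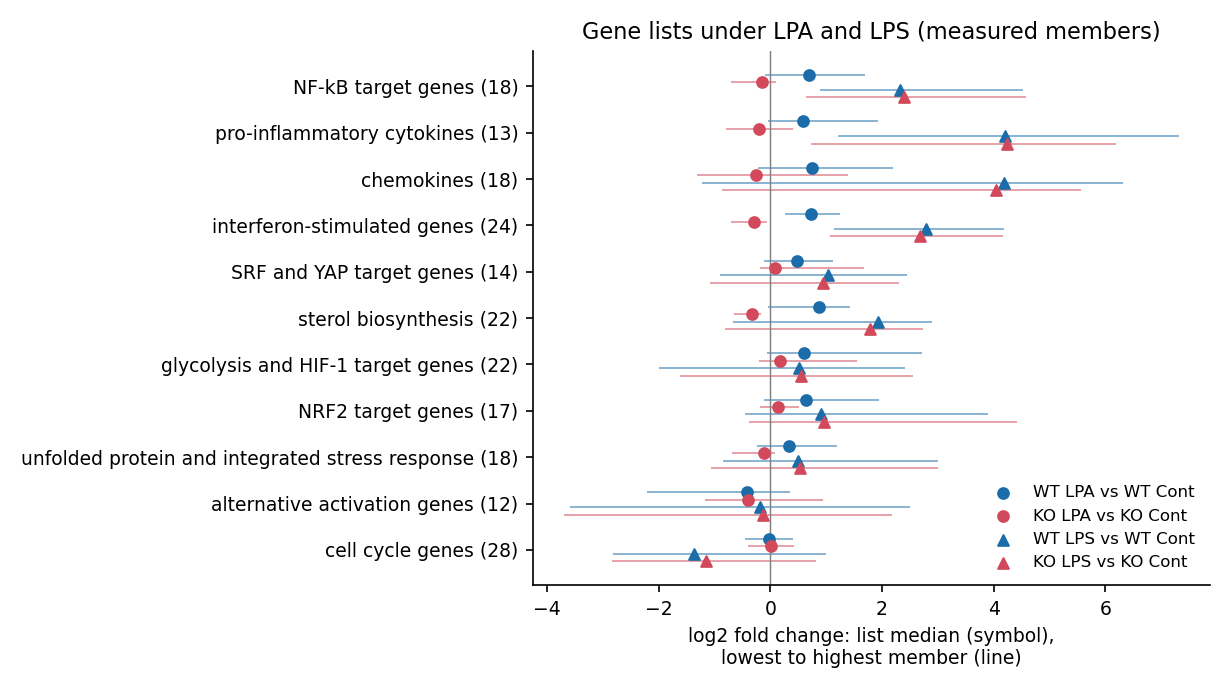
Median log2 change of 11 gene lists (symbols) in 4 comparisons, with lines from the lowest to the highest member. NF-kB target genes had medians of 0.69 with LPA in WT and -0.14 in KO; with scaling by library totals the LPS medians of the glycolysis list (-0.03) and the stress response list (-0.06) in WT turned negative.

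With LPA present, KO and WT macrophages differed in 5830 genes (2823 higher and 3007 lower in KO), 549 of them at least 2-fold. Lower in KO were Acod1 (-2.94 ± 0.23, n = 4 per group, edgeR adjusted p = 1.1e-08), Tnf (-2.42 ± 0.23, adjusted p = 1.2e-07), Cxcl10 (-2.46 ± 0.22, adjusted p = 5.1e-08) and Ak4 (-2.63 ± 0.32, adjusted p = 1.2e-06). Higher were Eps8 (2.29 ± 0.23, adjusted p = 1.2e-07) and Angptl4, which encodes an inhibitor of lipoprotein lipase (1.85 ± 0.19, adjusted p = 1.7e-07). NF-kB target genes were lower in KO in 16 of 18 (18 over the list alone, median -0.94, camera adjusted p = 4.5e-13 preset and 0.375 estimated). All 24 interferon-stimulated genes were lower (24 over the list alone, median -1.29, camera adjusted p = 3.8e-15 preset and 0.375 estimated), as were 20 of 22 sterol biosynthesis genes (20 over the list alone, median -1.20, adjusted p = 3.2e-08 preset and 0.375 estimated). Of 18 chemokines 12 were lower and 1 higher (the same over the list alone, median -1.28, camera adjusted p = 0.00125 preset and 0.375 estimated). Of 13 cytokines 7 were lower (8 over the list alone, median -0.68, camera adjusted p = 0.0262 preset and 0.475 estimated). Glycolysis and HIF-1 target genes were lower in 18 and higher in 1 (19 and 1 over the list alone, median -0.38, camera adjusted p = 8.8e-06 preset and 0.375 estimated). NRF2 target genes were lower in 13 (14 over the list alone, median -0.55, camera adjusted p = 6.1e-05 preset and 0.375 estimated). The stress response was lower in 14 and higher in 1 (the same over the list alone, median -0.50, camera adjusted p = 0.00123 preset and 0.375 estimated). SRF and YAP target genes were lower in 6 and higher in 2 (7 and 2 over the list alone, median -0.22, camera adjusted p = 0.0262 preset and 0.375 estimated). With scaling by library totals 67.4% of the called genes were higher in KO, against 48.4% here. Of markers of other cell types, Pecam1 (1.55 ± 0.31, edgeR adjusted p = 3.4e-04), Kmo (1.20 ± 0.28, 1.4e-03), Cxcr2 (0.94 ± 0.37, 0.038) and Mmp8 (0.60 ± 0.24, 0.042) were higher in KO. Hdc (-1.29 ± 0.20, edgeR adjusted p = 2.0e-05), Pf4 (-0.67 ± 0.11, 3.5e-05), Ppbp (-1.23 ± 0.33, 3.6e-03) and Cdh5 (-1.53 ± 0.45, 7.4e-03) were lower.

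LPS changed most measured transcripts in both genotypes: 9759 genes in WT (84.2%, 4709 rose and 5050 fell) and 9539 in KO (82.3%, 4554 and 4985). Tnf reached 2087 ± 141 CPM in WT and 2034 ± 332 CPM in KO (log2 change in KO 5.65 ± 0.26, n = 4 per group, edgeR adjusted p = 2.8e-14), and Acod1 9828 and 9356 CPM. The chemokine genes Ccl3 (5.37 ± 0.18 in WT, 5.03 ± 0.17 in KO), Ccl5 (5.27 ± 0.18 and 5.13 ± 0.18) and Ccl4 (6.02 ± 0.24 and 5.56 ± 0.24) rose alike. So did Mir155hg, the host gene of an inflammatory microRNA (7.15 in WT and 7.09 ± 0.24 in KO). Angptl4 (-7.70 ± 0.39 and -7.39 ± 0.42) and the receptor gene Gpr34 (-6.14 ± 0.55 and -5.86 ± 0.62) were among the largest falls. Of 9170 genes called in both genotypes 9168 moved the same way (r = 0.99 across genes, which are not independent replicates). With scaling by library totals the median of all genes was -0.59 in WT and -0.55 in KO, and 23.3% and 24.2% of the called genes rose, so small rises hold only relative to the other genes.

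With LPS, all 18 NF-kB target genes rose in both genotypes, over all genes and over the list alone (median 2.33 in WT and 2.39 in KO, camera adjusted p = 2.9e-08 and 9.5e-10 preset, 0.446 and 0.426 estimated). Nfkbiz rose by 3.69 ± 0.09 and 3.74 ± 0.10. In the other lists of this paragraph the counts were the same over the list alone. All 13 cytokines rose (median 4.20 in WT, camera adjusted p = 3.5e-05 and 6.8e-05 preset, 0.446 and 0.426 estimated, Il27 5.19 ± 0.21 and 5.32 ± 0.23). All 24 interferon-stimulated genes rose as well (median 2.68 in KO, adjusted p = 7.9e-08 and 1.1e-09 preset, 0.598 and 0.574 estimated, Rsad2 4.19 ± 0.22 and 4.17 ± 0.22). Of 18 chemokines 16 rose and 1 fell in both genotypes (median 4.19 and 4.04, camera adjusted p = 8.1e-05 and 6.8e-05 preset, 0.446 and 0.426 estimated). Sterol biosynthesis rose in 20 and fell in 1 in WT, and rose in 19 and fell in 1 in KO (median 1.93 and 1.78, camera adjusted p = 1.6e-04 and 4.1e-04 preset, 0.598 and 0.58 estimated, Insig1 2.19 ± 0.16 and 2.07 ± 0.16). Immediate-early genes rose in 16 and fell in 4 in WT, and in 14 and 4 in KO (camera adjusted p = 0.0229 and 0.0343 preset, 0.598 and 0.574 estimated, Egr1 2.80 ± 0.17 and 2.55 ± 0.18). SRF and YAP target genes rose in 10 and fell in 3 in both (camera adjusted p = 0.0361 and 0.0384 preset, 0.598 and 0.574 estimated, Tpm4 2.44 ± 0.09 and 2.31 ± 0.09). NRF2 target genes rose in 11 and fell in 2 in WT, and in 12 and 1 in KO (camera adjusted p = 0.0471 and 0.00783 preset, 0.71 and 0.574 estimated, Slc7a11 3.90 ± 0.24 and 4.42 ± 0.26). Antigen presentation genes rose in 14 and fell in 4 in both (camera adjusted p = 0.0471 and 0.0203 preset, 0.598 and 0.574 estimated, Tap2 2.08 ± 0.11 and 2.02 ± 0.11).

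Glycolysis and HIF-1 target genes rose in 16 and fell in 2 with LPS in both genotypes (15 and 2 over the list alone in WT, median 0.52 in WT and 0.55 in KO, camera adjusted p = 0.0229 and 0.0078 preset, 0.598 and 0.574 estimated, Slc2a1 2.41 ± 0.14 and 2.56 ± 0.15). The stress response rose in 12 and fell in 3 in WT (the same over the list alone, median 0.49, camera adjusted p = 0.0471 preset and 0.612 estimated, Ppp1r15a 3.01 ± 0.10). By library totals these WT medians were -0.03 and -0.06, so as groups they rose only relative to other genes. Cell cycle genes fell in 21 and rose in 2 of 28 in WT (the same over the list alone, median -1.37, Mcm2 -2.26 ± 0.15, Mcm7 -2.74 ± 0.32), which camera did not call (adjusted p = 0.103 preset and 0.779 estimated). Among LPA receptors, Lpar1 rose from 4.12 to 58.1 CPM (3.81 ± 0.18, edgeR adjusted p = 1.3e-14), whereas Lpar5 (-4.08 ± 0.20, adjusted p = 2.1e-14) and Lpar6 (-4.00 ± 0.18, adjusted p = 1.5e-14) fell. KO cells did the same (3.56 ± 0.19, -4.19 ± 0.23 and -3.80 ± 0.19). None of the 11 lists that camera called in WT and the 10 in KO passed with the estimated correlation, and 8 of the 11 held with median-ratio size factors.

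The LPS effect differed between genotypes in 0 genes by edgeR (698 with an unadjusted p below the threshold, smallest adjusted p = 0.231). Median-ratio size factors gave 0 as well (680 unadjusted), and DESeq2 called 4: Grb2 (-0.20), Inppl1 (-0.29), Slc9a9 (0.39) and Peg13 (0.55). The LPS response score over 10217 genes rose by 1.07 (SE 0.0233) in WT and 1.03 (SE 0.0369) in KO, or 96.6% of WT, a difference of -0.0365 (exact permutation p = 0.399). With the preset correlation camera called SRF and YAP target genes (median -0.14, adjusted p = 0.0281), sterol biosynthesis (-0.19, adjusted p = 0.0484) and NRF2 target genes (0.19, adjusted p = 7.6e-04). It called none of them with an estimated correlation (adjusted p = 0.981 for each), nor did fry, and none of their members was called over all genes or over the list alone. Adjusted over their lists alone, Hk1 (-0.29 ± 0.07), Pfkfb3 (-0.34 ± 0.10), Dusp1 (-0.78 ± 0.22) and Hdc (-0.51 ± 0.23) passed with a lower and Abca1 (0.30 ± 0.08) with a higher LPS effect in KO. None of them was called over all genes, and these p-values were not adjusted across the 25 lists. Hdc is the only measured gene of its list, so its p was not adjusted at all.

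Directly compared with LPS present, KO and WT differed in 330 genes (80 higher and 250 lower in KO), 7 of them at least 2-fold. Lower in KO were the endothelial lipase gene Lipg (-1.22 ± 0.17, n = 4 per group, edgeR adjusted p = 9.9e-04) and the endothelin gene Edn1 (-0.95 ± 0.25, adjusted p = 0.041). So were the glycolytic regulator gene Pfkfb3 (-0.55 ± 0.07, adjusted p = 3.2e-04) and Il18 (-0.47 ± 0.12, adjusted p = 0.029). Higher were the imprinted transcript Peg13 (0.65 ± 0.08, adjusted p = 8.3e-05) and the arrestin gene Arrb1 (0.48 ± 0.08, adjusted p = 2.7e-03). With scaling by library totals 78.2% of the called genes were higher in KO (381 up, 106 down), against 24.2% here, so which side predominates depends on the scaling. The count is not firm, as DESeq2 called 581 and a fit of only these 2 groups 131. With the replicate number in that fit it was 0, although these numbers do not pair libraries across genotypes. A fit without 1 library gave 577 (WT LPS 1), 160 (WT LPS 2), 65 (WT LPS 3), 74 (KO LPS 3) and 190 genes (KO LPS 4). Camera called interferon-stimulated genes (1 fell, 2 over the list alone, Isg20 -0.59 ± 0.16, median -0.28, adjusted p = 1.7e-04 preset and 0.673 estimated) and immediate-early genes (1 fell, 2 over the list alone, Dusp1 -0.68 ± 0.16, median -0.14, adjusted p = 0.00578 preset and 0.673 estimated). The single mast cell gene Hdc fell as well (-0.55 ± 0.13, adjusted p = 0.00578 preset and 0.0811 estimated). Camera also called sterol biosynthesis (median -0.19, adjusted p = 0.0199 preset and 0.814 estimated) and SRF and YAP target genes (-0.11, adjusted p = 0.0394 preset and 0.673 estimated). Antigen presentation (-0.16, adjusted p = 0.0173 preset and 0.673 estimated) and NRF2 target genes (0.21, adjusted p = 0.00706 preset and 0.673 estimated) were called too. None of the members of these 4 lists was called over all genes or over the list alone, while 6 chemokines, none called over all genes, were lower over the list alone. Of the 7 lists that camera called here, fry called only the single gene Hdc against no change.

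In WT macrophages LPA and LPS moved genes the same way. Of 4827 genes that both treatments changed, 4623 (95.8%) went in the same direction, and 204 in opposite ones (102 rose with LPA and fell with LPS, 102 the reverse). Independent lists of these sizes would share 2170. Both effects were taken against the same untreated libraries, so the overlap was also computed with separate untreated libraries for each, which gave a mean of 3247 (2781 to 3763 over 6 draws, 1449 if independent). WT LPA against KO LPS, which have no library in common, shared 4636 (2120 if independent). The log2 changes of the 2 treatments correlated across genes at r = 0.79 (0.75 with separate untreated libraries, 0.48 in counts simulated without any effect, genes are not independent replicates). In KO cells, of 274 genes called with both LPA and LPS, 77 went the same way and 197 the opposite way, where independent effects would give 124 the same way. Both KO effects share the untreated KO libraries. LPA in KO against LPS in WT, which have no library in common, gave much the same. Of 272 genes called in both, 74 went the same way (127.1 if independent) and 198 the opposite way.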

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

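Of the tests in this part, the 2 on endotoxin, the 1 on spread between libraries, the splits of numbered cultures and the look at regroupings that did not keep the treated grouping were chosen after the results had been seen. The expectations for the others, among them that a result reached by under 5% of regroupings is not put down to chance, were written before those tests were run.

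LPA moved WT transcripts in the direction of LPS. If RNA or reads of LPS libraries had been mixed into the WT LPA libraries, genes raised and genes lowered by LPS would imply the same share of LPS material. The share implied by 839 lowered genes (16.4% to 51.8%) exceeded that implied by 615 raised genes (6.97% to 17.5%) by at least 2.35-fold in every WT LPA library, against a bound of 1.5, so simple mixing does not account for the pattern. If endotoxin in the LPA preparation had reached both genotypes, the 567 genes that LPS raised at least 4-fold in KO would have risen there too. Yet their median change with LPA in KO (-0.20) was -0.262 of that in WT (0.75), with 5 genes up and 22 down in KO. That expectation takes KO cells to answer weak LPS as WT cells do. LPS was given at 10 ng/mL only, so a genotype difference in the answer to weak LPS is not covered by this test. Endotoxin in the WT LPA cultures alone cannot be told apart from an LPA effect that needs Gpr35, since 4.23% of the genes called with both treatments (204 of 4827) moved in opposite directions and weak LPS was not among the treatments.

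Fewer genes changed with LPA in KO than in WT. Lower sequencing depth of the KO libraries would give a ratio near 1 after thinning to equal depth, but WT then had 4463 genes and KO 278, a ratio of 16.05 (17.0 with all counts). A larger spread between KO libraries around an equal response would leave the response score unchanged, but the KO score was 0.247 of the WT score (exact permutation p = 0.00122). Both explanations were excluded by these tests, which is consistent with an LPA response that depends on Gpr35 or on something else that differs between the 2 sets of cultures.

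With LPS 330 genes differed between KO and WT, and without treatment 1. The interaction, which tests directly whether LPS changed the genotype difference, called 0 genes (smallest edgeR adjusted p = 0.231). The counts of 330 and 1 therefore do not show that the difference needs LPS. Depth did not account for the 330 genes, since thinning left 243, a ratio of 1.36. A lane or library batch that goes with genotype would shift the same genes without treatment too, and their median signed difference was 0.0529 without treatment, 0.141 with LPA and 0.310 with LPS, and the ratio of the untreated to the LPS median was 0.171. That 276 of the 330 genes (83.6%) had the same sign without treatment is in line with some of the difference being common to all treatments, and choosing genes by their difference with LPS makes that difference look larger. A batch that goes with genotype is therefore not excluded by these values, and a batch that acted on the LPS libraries alone stays open too.

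Relabelling the libraries tested whether groups formed at random could give as many genes. For the LPA effect in WT 1 of 35 splits of the 8 libraries, the real one, reached 5165 genes, and the highest other gave 4114, with WT LPA 3 and WT Cont 1 exchanged. In KO 1 of 35, again the real one, reached 304, and the highest other gave 22. For LPS in WT 1 of 35 reached 9759 and the highest other gave 0. In KO with LPS 1 of 35 reached 9539 and the highest other gave 3065, with KO LPS 4 and KO Cont 2 exchanged. Between genotypes with LPA 1 of 35 reached 5830 (highest other 4858, with KO LPA 2 and WT LPA 3 exchanged), and with LPS 1 of 35 reached 330 (highest other 205). In each of these 6 comparisons only the real split reached the count, which is under the limit set before if libraries are taken as independent. For the treatment effects that is doubtful, since libraries with the same number correlated within a genotype. Only 8 of the 35 splits part every such pair. With so few, even the real split alone cannot fall under that limit, so these 8 cannot decide about chance. Between untreated genotypes 2 of 35 splits gave as many as the 1 gene found (highest other 1), so for the count, though not for Gpr35 itself, chance cannot be excluded. For the difference of the LPA effect 4 of 100 regroupings reached 3301 genes (highest other 4223). That is under the limit set before, which again takes the libraries as independent. The 3 others kept the treated libraries grouped by genotype, the highest without that gave 2124, and over the 35 splits of numbered cultures only the real one reached the count (highest other 0). For the difference of the LPS effect 100 of 100 regroupings reached the count of 0 (highest other 7), as any regrouping must, so this says nothing about chance.

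A library was looked for that stood apart from the other 3 of its group by a Dixon test, in 242 groups of values. Chance picks out about 1 in 20 groups, or 12.1 of them, and 8 were found, so no single one is evidence of a fault. KO LPA 2 had 11% of its counts in its 10 largest genes (others 10.67% to 10.7%). In list scores, cytokines stood apart in WT Cont 2 (-1.31, others -1.52 to -1.49), steroid hormone synthesis in WT LPA 4 (0.337, others 0.116 to 0.129) and alternative activation genes in WT LPA 3 (-0.0660, others -0.302 to -0.279). Dendritic cell markers did so in KO LPS 2 (-0.844, others -0.439 to -0.396) and the mast cell marker in KO LPA 2 (-2.50, others -1.83 to -1.75). Lpar6 was 138.8 CPM in WT LPA 3 (others 74.8 to 81.6 CPM), and Col1a2 was 5.40 CPM in WT LPS 1 (others 0.673 to 1.34 CPM).

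Results that differed between the genotypes were picked out as such, and all concern the LPA effect in KO minus that in WT. They were the 3301 genes and the response score difference of -0.377. The list medians were -0.94 for NF-kB target genes, -0.72 for cytokines, -1.05 for chemokines, -1.035 for interferon-stimulated genes, -0.32 for SRF and YAP target genes and -1.19 for sterol biosynthesis. They were -0.40 for glycolysis, -0.60 for NRF2 target genes and -0.47 for the unfolded protein and integrated stress response. Single genes with a higher effect in KO were Gpr82 (2.115), Rnf150 (1.93), Eps8 (1.91), Slco2b1 (1.83), Fam214a (1.71), Abcd2 (1.71), Lpar6 (0.91) and Mertk (0.65). Genes of inflammation with a lower effect were Acod1 (-2.81), Cxcl2 (-2.48), Tnf (-2.39), Tarm1 (-2.35), Fpr2 (-2.30), Fpr1 (-2.28), Nfkbiz (-1.18), Sod2 (-1.64), Cd40 (-1.64), Ccl4 (-1.76), Cxcl10 (-2.04), Csf1 (-1.16) and Cd14 (-0.80). Interferon-stimulated and metabolic genes with a lower effect were Ifit1 (-1.49), Rsad2 (-1.77), Insig1 (-1.18), Slc2a1 (-0.97), Pgk1 (-0.68), Txnrd1 (-0.79) and Slc7a11 (-1.44). Herpud1 (-0.80), Atf4 (-0.71), Tpm4 (-1.04), Vcl (-0.76) and Lpar1 (-1.995) also had a lower effect. Not all of these are weaker responses in KO, since Herpud1 fell with LPA in KO (-0.68), as did Cxcl10 (-1.11), Nfkbiz (-0.57) and Cd40 (-0.70).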

How the results depend on the processing

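The counts without WT LPA 3 and KO Cont 4 were named after the results had been seen, as were scaling by library totals and fry, and the other alternatives were fixed before. The cause of any change below was not tested.

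The number of genes that LPA changed in KO (304) was 462 with DESeq2, 554 with the replicate number in the fit (300 of the 304 shared), 531 with that fit on thinned counts, and 168 to 310 without 1 library. The difference of the LPS effect between genotypes (0 genes) was 4 with DESeq2, 1 with the replicate number on thinned counts (Napepld, -1.10) and 0 to 1 without 1 library (Slc8b1, -0.44, without WT LPS 1). The number of genes between KO and WT with LPS (330) was 581 with DESeq2, 131 in a fit of the 2 groups, 0 with the replicate number in that fit, 4 with it on thinned counts, and 65 to 577 without 1 library. Replicate numbers do not pair libraries across genotypes, so the 0 is no evidence against the 330. The number of gene lists called over the 9 comparisons (79) was 0 with an estimated correlation, 76 with median-ratio size factors and 54 with fry, which tests against no change and not against other genes.

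Without 1 library the other counts were 3792 to 6083 for LPA in WT, 2259 to 4632 for the difference of the LPA effect, 9487 to 9639 and 9248 to 9522 for LPS in WT and KO, and 4790 to 6624 between genotypes with LPA. Gpr35 without treatment lay between -4.49 and -3.97. Of 546 named gene results 543 had an adjusted p under DESeq2, and all of these kept their call. Among the 542 that were called, 540 were still called in the same direction. Calls were kept under median-ratio size factors in 544 of 546, on thinned counts in 525 of 546, and with the replicate number in 514 of the 544 that could be compared. Without 1 library 4808 of 5032 values kept their call and 216, in 47 of the 546 results, were weaker.

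Only Gpr35, in comparisons where it was never called, changed sign. Its difference of the LPA effect (0.06) was -0.30 on thinned counts and -0.35 to 0.41 without 1 library, and its LPA change in KO (-0.27) was -0.68 to 0.0801 without 1 library. These rest on 0 to 5 counts per KO library.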

Other observations

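The genes described in this part were chosen after their values had been seen, the TGF-beta test was fixed before its held-out genes were looked at, and the cell cycle test was chosen after.

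Some genes answered LPA in the same direction in both genotypes. There were 110 of them, where independent calls would give 68.4, and 49 more went opposite ways (r = -0.01 across all genes). Part of the 110 may thus be shared by chance. Of the 110, 74 rose and 36 fell. LPS in WT also changed 92 of them, 56 in the same direction and 36 (39.1%) in the opposite one. Opposite directions were not particular to these genes, since 198 of 272 genes called with LPA in KO and LPS in WT went opposite ways. Raised by LPA in both genotypes and lowered by LPS were 24 genes. Among them were Olfml3 (1.19 in WT, 2.24 in KO, -1.78 with LPS in WT), the proteoglycan gene Cspg4 (1.00, 1.44 and -2.26), the junction protein gene Cgnl1 (0.94, 0.96 and -2.06) and the sulfotransferase gene Chst3 (0.80, 1.12 and -1.48). The immediate-early gene Fos (0.75, 0.71 and -1.36) and the TGF-beta receptor gene Tgfbr1 (0.27, 0.66 and -1.61) followed the same course, as did the formin genes Fmnl3, Inf2 and Fhod1. The rise with LPA was larger in KO for Olfml3 (interaction, edgeR adjusted p = 0.0153), Tgfbr1 (0.0466) and Fmnl3 (0.00276). It was not called as different for the other genes named here.

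Transcripts of LPA receptors, and of the related receptor gene Gpr132, were measured too, in CPM that are not corrected for gene length. In untreated cells Lpar6 stood at 129.6 CPM in WT and 126.4 CPM in KO, Gpr132 at 31.1 and 32.9 CPM, Lpar5 at 25.4 and 27.0 CPM, Lpar1 at 4.12 and 4.66 CPM, and Lpar2 at 2.83 and 2.58 CPM. With LPA, Lpar1 was 9.67 CPM in WT and 2.72 CPM in KO, and Lpar6 93.4 and 170.9 CPM. LPS left Lpar5 at 1.49 and 1.503 CPM and Lpar6 at 8.12 and 9.10 CPM, and Lpar1 at 58.1 and 55.0 CPM.

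LPA in KO raised several genes known to follow TGF-beta. Skil, which encodes a feedback inhibitor of SMAD proteins, rose by 0.68 ± 0.08, Olfml3 by 2.24, Spsb1 by 1.29 and Smad6 by 1.005 ± 0.27. One explanation is an LPA effect on TGF-beta and SMAD target genes that does not need Gpr35, for example through Lpar receptors and the release of TGF-beta at the cell surface, and another is a few stromal cells in the cultures. A list of 24 other TGF-beta and SMAD target genes was written without a look at their values. It held no gene among the largest changes with LPA in KO. It did hold Sox4, among the largest rises in KO against WT with LPA (1.66), which was not called with LPA in KO (0.49). Of 23 measured members 4 rose and none fell with LPA in KO (Nedd9 0.60, Tgfbr1 0.66, Tgif1 0.26, Ski 0.25). Over the list alone 7 rose and none fell, and the median was 0.22. The rotation test fry gave p = 3.21e-07 in KO (5.65e-07 with the replicate number) and p = 0.00776 in WT, and camera in KO with an estimated correlation p = 1.72e-05. The held-out list goes with the first explanation but does not exclude the second. Col1a1 (1.99) and Col1a2 (2.12) were higher in the same libraries without passing the test. Pecam1 rose there too (1.29), but is uncertain as a sign of stromal cells. LPS lowered it in WT (-2.68), where Col1a1 was not called as changed (0.497, edgeR adjusted p = 0.459). In KO with LPS both genes were lower in the mean (Pecam1 6.78 to 1.11 CPM, Col1a1 0.512 to 0.292 CPM). Both explanations therefore stay open. In WT 9 members of the list rose with LPA and 2 fell, with a median of 0.07. The effect was larger in KO for Spsb1 (difference 0.95, edgeR adjusted p = 0.00386) and Olfml3 (1.06, adjusted p = 0.0153) and was not called as different for Skil (-0.14, adjusted p = 0.344) and Smad6 (-0.28, adjusted p = 0.588), which rose in WT as well (0.82 and 1.28). Repeating the LPA treatment on sorted macrophages of both genotypes, with and without an inhibitor of the TGF-beta receptor kinase, would separate the 2 explanations.

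Cell cycle transcripts differed between cultures with the same replicate number in a way common to all treatments. After subtraction of group means, the mean cell cycle score over the 3 treatments was -0.308, 0.0631, 0.497 and -0.251 for WT 1 to 4, and 0.400, -0.963, -0.0191 and 0.583 for KO 1 to 4. Cultures of one number may share a state set before treatment, such as density or the donor animal, or they may have been handled together afterwards. The exact permutation p of the spread of these means was 1.175e-04 over 331776 arrangements (0.0174 for WT and 0.00174 for KO alone). The list was looked at because it showed this pattern, so this p restates the observation and supports neither explanation. Chance in the choice of the list and both explanations remain open, and a record of which cultures came from which animal would separate the 2 explanations.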
